A study of Mus musculus with 39 samples.

How the data were processed

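The data are RNA sequencing values of endothelial cells from whole brains of C57BL/6 mouse pups. Cells were released with an enzymatic dissociation kit and captured on beads coated with a PECAM antibody, and libraries were made with the TruSeq RNA kit, version 2, per the labels' protocols. Per the labels, tamoxifen was given at 300 µg on postnatal days 1 to 3, or at 100 µg on day 4 in the Alk1 cohort, and IgG or LC10 at 30 µg on days 2 and 4. The 39 libraries used form 9 groups, of 5 each in the untreated Smad4, Alk1 and Eng cohorts and of 3 each for IgG wild type, IgG mutant and LC10 mutant. All mutants carried Cre and no wild type did.

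The deposited tables, 1 per cohort and 1 per antibody, hold a normalized signal per gene and library, mapped to mm10 per the submitters' processing notes, in place of the raw counts that the labels name. The aligner, the counting tool and the method of normalization are not given in the sources used here. Only 14.3 to 24.6% of the values of a library lay within 0.05 of a whole multiple of its smallest step. Among the low values alone the share was 38.8 to 84%, still short of all. A test made for counts was therefore not used, although the plan assumed counts. From that step, fragments per library were inferred at 11.11M to 30.92M, with value sums of 25.5M to 42.83M and 16125 to 17708 genes above 0. Each table held 24972 genes, of which 26 with date-like or repeated names were left out, leaving 24946 in all tables. Of the symbols, 98.1% matched gene names of GENCODE M21, from which coordinates were taken. Columns of the untreated cohorts were joined to samples by group only, so replicate numbers there are file order. A further 3 columns, LC10-treated wild types, match no sample described and were not used. Some column names carry a library code, namely L146 in the Smad4, L219 in the Alk1, and L210 or L216 in the Eng cohort. No library was high or low in both the X-linked Xist and the Y-linked Ddx3y, and no pair of columns was identical, with a Pearson r across 12381 genes, which are not independent replicates, of 0.9251 to 0.9959.

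Values were transformed as log2 of the value plus 2 and used without further scaling. Genes with a value of at least 20 in at least 5 libraries (3 in the antibody cohort) were tested with limma 3.58.1 in R 4.3.3 with an intensity trend, at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount makes the fold changes of genes with low values too small. The tables were normalized separately, so tests were made only within a table. Each untreated cohort was fitted alone. For IgG the 3 LC10 libraries entered the fit as a group of their own. They added to the estimate of spread and counted in the filter on low values, but not in the contrast. Genotype effects were compared between cohorts as differences of within-table effects in a joint fit of the 30 untreated libraries. LC10 levels were brought to the scale of the IgG table by the median of ratios over the 9 antibody libraries and compared without a test, since treatment and table are confounded. The signature score of a library is the mean log2 value of genes called higher in untreated Smad4 mutants minus that of genes called lower.

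For gene groups, 33 lists with 514 members were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Values were adjusted over the 33 lists of a comparison. The lists of p53 targets and glucocorticoid-responsive genes were chosen after values had been seen, were first run in shorter forms of 33 and 20 genes and then restored to 45 and 25, and are adjusted over 14 tests of their own. Overlaps were tested with Fisher's exact test, one-sided, against the genes tested in every cohort. Genes named in the text are Smad4, Acvrl1, Eng, Angpt2 and Tek, the 6 largest rises and falls of a comparison, up to 4 members per list with the smallest adjusted p, the 10 genes of largest shared change, the 3 largest differences each way between cohorts and the 6 largest each way between LC10 and IgG mutants. The largest changes were taken among genes with a mean log2 share, in ppm of the library sum, of at least 2 and no overlap between groups. Some genes that meet this rule are not reported here.

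The procedure was tested on simulated libraries in which 100 genes each were changed 1.5-fold and 2-fold. Each gene was drawn around its mean over all libraries of a table, with the real spread within groups. Every library had a step of about 2, so the real differences in depth (11.11M to 30.92M fragments) were not copied. The shares below leave those differences out. At 1.5-fold 59, 60, 74 and 61% were called in the right direction in the Smad4, Alk1, Eng and IgG comparisons, and 66, 76, 81 and 72% at 2-fold. For the differences between cohorts the shares were 52, 42 and 45% at 1.5-fold and 63, 69 and 74% at 2-fold, for Smad4 against Alk1, Smad4 against Eng and Alk1 against Eng. Among the unchanged genes of the same libraries 4, 10, 4 and 12 were called in the Smad4, Alk1, Eng and IgG comparisons, and 27, 6 and 11 for the differences between cohorts. With no gene changed, limma called none in any comparison.

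Alternatives were adjusted p thresholds of 0.01 and 0.1, pseudocounts of 1 and 10, median of ratios, total and quantile scaling, array weights, no filter on low values, the joint fit, the fit of the 2 IgG groups alone, leaving out each library, Xist as a covariate, the library code as a term, libraries of 1 code only, and the mean log2 value of astrocyte, oligodendrocyte and neuron markers as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.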

Results

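Messenger RNA was sequenced from brain endothelial cells of mouse pups in which endothelial cells had lost Smad4, Alk1 (gene symbol Acvrl1) or Eng. These genes encode a signal transducer, a receptor and a co-receptor of the BMP9 pathway, and their loss serves as a model of hereditary haemorrhagic telangiectasia (HHT), a disease of malformed vessels. Each of the 3 untreated cohorts held 5 mutants, which carried an endothelial, tamoxifen-inducible Cre, and 5 wild types, which carried the floxed gene without Cre. Further Smad4 pups received an antibody, with 3 wild types and 3 mutants given control IgG and 3 mutants given LC10, an inhibitor of angiopoietin-2. That makes 39 libraries in 9 groups. Tissue was taken on postnatal day 7, or on day 6 in the Alk1 cohort. The depth, inferred from the spacing of the low values in each library, ran from 11.11M to 30.92M fragments, and 16125 to 17708 genes had a value above 0. All values are normalized expression values, given as mean ± SD, and log2 fold changes are given ± SE, with n = 5 per group in the untreated cohorts and n = 3 per group in the antibody cohort.

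The targeted genes came first, as a check on the genotype labels. Smad4 (mm10 chromosome 18, 73639009 to 73703780) stood at 1820 ± 113 in the 5 Smad4 mutants and 5700 ± 264 in the 5 wild types, a log2 fold change of -1.65 ± 0.06 (adjusted p = 2.18e-08). The mutants lay between 1676 and 1916 and the wild types between 5258 and 5903. In the antibody cohort the IgG mutants held 3030, 2099 and 1817 and the IgG wild types 5625 to 5975, and the LC10 mutants lay between 1535 and 1708 in their own table. Eng (chromosome 2, 32646595 to 32682669) stood at 8613 to 11508 in the Eng mutants and 60151 to 70402 in their wild types (log2 fold change -2.65 ± 0.08, adjusted p = 1.14e-09). Acvrl1 (chromosome 15, 101128522 to 101145336) lay between 12441 and 15809 in the Alk1 mutants and between 14197 and 16755 in their wild types, a log2 fold change of -0.12 ± 0.08 (adjusted p = 0.279). That difference passed the threshold when each library was divided by its total (-0.19, adjusted p = 0.0304) and after quantile normalization (-0.25, adjusted p = 0.00854). The labels do not say which part of Acvrl1 was removed, so its whole-gene value does not check the Alk1 genotypes.

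**Figure D1:**
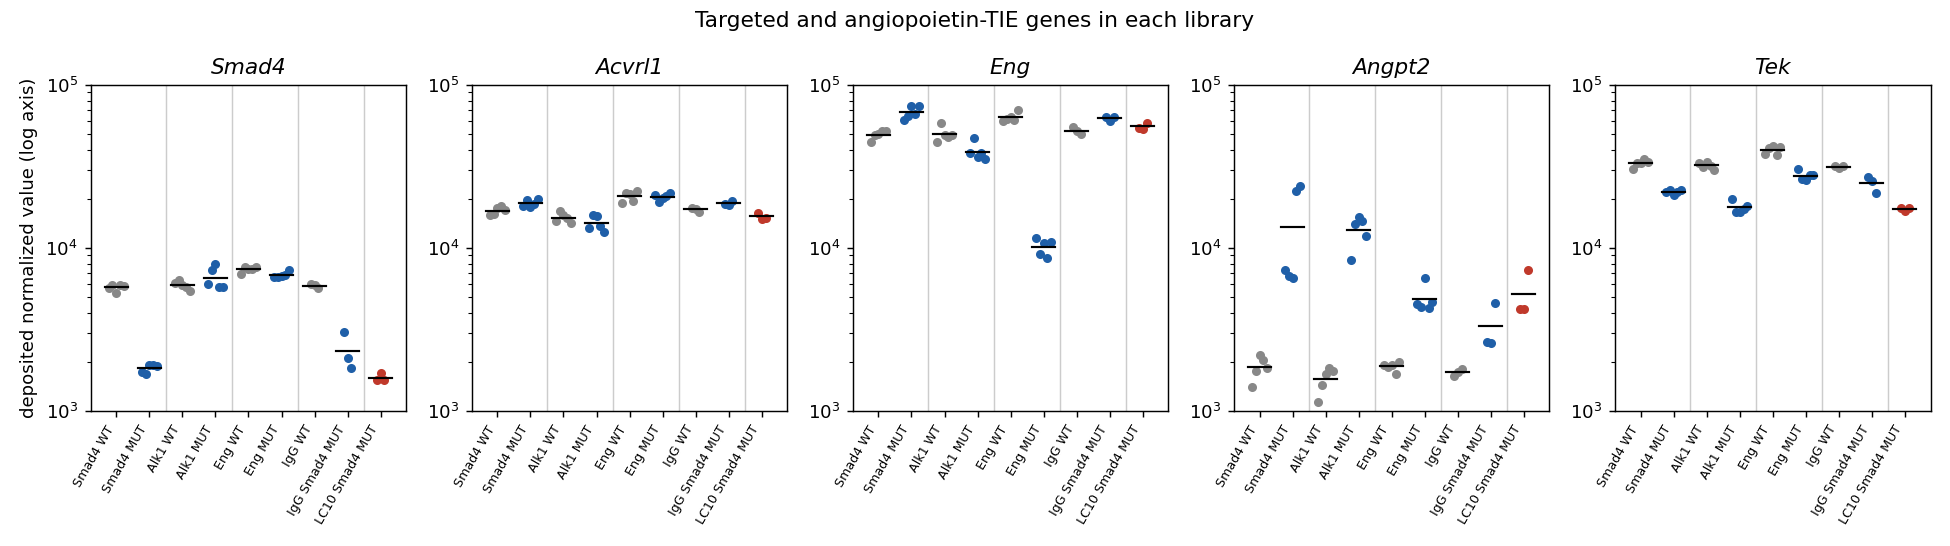
Deposited normalized value (log axis) of Smad4, Acvrl1, Eng, Angpt2 and Tek in each library, with wild types in grey, mutants in blue, LC10-treated mutants in red and group means as black lines. Smad4 and Eng separated mutants from wild types in their own cohorts, Acvrl1 did not in the Alk1 cohort, and Angpt2 was above its wild types in every mutant library of the 3 untreated cohorts.

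The first question was what the loss of each gene changed in the endothelium, and Angpt2 and its receptor Tek were named in advance because the antibody targets this pathway. Angpt2 (chromosome 8, 18690263 to 18741562), a ligand that antagonizes Tek in resting vessels, rose in the mutants of all 3 untreated cohorts. It went from 1840 ± 308 to 13400 ± 8950 after loss of Smad4 (log2 fold change 2.61 ± 0.38, adjusted p = 0.000491). It went from 1570 ± 286 to 12900 ± 2800 after loss of Alk1 (3.03 ± 0.17, adjusted p = 4.91e-07). After loss of Eng it went from 1870 ± 120 to 4850 ± 960 (1.36 ± 0.10, adjusted p = 4.83e-06). Tek (chromosome 4, 94739289 to 94874976) fell in all 3, by 0.58 ± 0.05 on the log2 scale in the Smad4 (adjusted p = 1.46e-05), 0.86 ± 0.07 in the Alk1 (adjusted p = 2.6e-06) and 0.53 ± 0.05 in the Eng cohort (adjusted p = 4.27e-05). Eng itself rose after loss of Smad4 (0.45 ± 0.08, adjusted p = 0.00167) and fell after loss of Alk1 (-0.36 ± 0.10, adjusted p = 0.0116). The latter call was lost among the 3 mutants and 3 wild types without a library code (adjusted p = 0.165). Smad4 was called lower in the Eng cohort by a small margin (-0.12 ± 0.04, adjusted p = 0.0495). That call was lost without Eng mutant 1, 2, 3 or 4 (adjusted p = 0.102, 0.101, 0.106 and 0.0895), without Eng wild type 2, 3, 4 or 5 (adjusted p = 0.113, 0.1, 0.0913 and 0.0951). It was lost as well in a joint fit of the 30 untreated libraries (adjusted p = 0.351), without the filter on low values (adjusted p = 0.0665) and with Xist in the fit (adjusted p = 0.0652). The angiopoietin-TIE list as a whole was not called by camera in any cohort, and in the Smad4, Alk1 and Eng cohorts its median was negative (-0.16, -0.29 and -0.18) while its mean was slightly positive (0.01, 0.05 and 0.05). By fry it went down on balance in all 3 untreated cohorts (adjusted p = 0.000906, 0.00657 and 0.0228).

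In the Smad4 mutants, genes of vessel sprouting and matrix rose and genes of capillary transport fell. Pgf, a ligand of the VEGF family, rose by a log2 fold change of 4.16 ± 0.25 (adjusted p = 1.11e-06). The receptor gene Eda2r (5.16 ± 0.24, adjusted p = 1.56e-07) and Phlda3, an inhibitor of AKT signalling (3.42 ± 0.09, adjusted p = 2.36e-09), were also among the 6 largest rises. So were the phosphatase gene Ppef1 and the zinc receptor gene Gpr39. Among the 6 largest falls were Ddc, which encodes an amine-forming decarboxylase (-2.87 ± 0.15, adjusted p = 2.86e-07), the ion channel gene Best1 (-2.79 ± 0.22, adjusted p = 6.68e-06) and Id1, a direct target of BMP signalling (-2.50 ± 0.11, adjusted p = 1.32e-07). In all, 4620 of 14012 genes were called, 2409 higher and 2211 lower, of which 1032 changed at least 2-fold (281 higher and 751 lower), and 6364 had an unadjusted p under 0.05. The share of calls that were higher, 52.1%, became 37.2% when each library was divided by its total. The count was 2461 in the 3 mutants and 3 wild types without a library code and 2098 with the glial and neuronal marker level in the fit. The 2 groups did not overlap for 22.8% of genes, against 0.794% by chance.

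By pathway, the BMP9-ALK1 response list went down after loss of Smad4, with 11 of its 18 genes lower and 4 higher (13 and 4 adjusted over the list alone). Its median was -0.50 and its adjusted p by camera 0.00971, or adjusted p = 0.323 with an estimated correlation. Id1 and Id2, transcriptional regulators downstream of BMP receptors, fell while the cell cycle inhibitor Cdkn1a and the Notch-modifying enzyme Lfng rose. Of the 22 tip cell genes, which mark the leading cells of sprouts, 20 rose (20 adjusted over the list alone), with Apln, Mcam and Lama4 among them (median 0.95, adjusted p = 1.75e-10, but adjusted p = 0.389 with an estimated correlation). Cell cycle genes rose in 30 of 37 cases (33 adjusted over the list alone), among them Ube2c, Rrm2 and Plk1 (median 0.45, adjusted p = 4.6e-14, or adjusted p = 0.323 with an estimated correlation). Basement membrane and matrix genes rose in 17 of 28 cases and fell in 2 (17 and 2 adjusted over the list alone). Col18a1 was up at 1.97 ± 0.09 and Col15a1 down at -1.14 ± 0.14 (adjusted p = 4.66e-05 for the list, or adjusted p = 0.323 with an estimated correlation). Interferon response genes such as Ifit1, Oasl2 and Rsad2 rose in 19 of 22 cases (20 adjusted over the list alone; median 1.16, adjusted p = 9.53e-08, or adjusted p = 0.505 with an estimated correlation). Rsad2 lost its call with the glial and neuronal marker level in the fit (adjusted p = 0.0656).

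Transport and barrier genes went the other way in the Smad4 mutants. Of 13 capillary genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), including the transporter genes Slc22a8 (-1.25 ± 0.06), Slc16a1 (-1.37 ± 0.11) and Slco1c1 (-1.16 ± 0.10). The list had an adjusted p of 9.27e-06, or adjusted p = 0.271 with an estimated correlation. Of 26 blood-brain barrier genes 15 fell and 3 rose (16 and 5 adjusted over the list alone), with Jam2 lower (adjusted p = 0.000256, or adjusted p = 0.389 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 of 27 cases and fell in 3 (16 and 4 adjusted over the list alone), with Adm and Slc2a1 up and Ndrg1 down. That list's adjusted p of 0.0119 became 0.362 with the glial and neuronal marker level in the fit, 0.0722 by fry, which asks whether the genes move one way on balance, and adjusted p = 0.564 with an estimated correlation. The caveolae list was called up (Plvap 0.82 ± 0.07; adjusted p = 0.00342, or adjusted p = 0.389 with an estimated correlation, and 0.0816 with the marker level in the fit). Camera called none of the Notch, VEGF, arterial, venous and integrin lists, which had members in both directions, while fry called the Notch (adjusted p = 0.00775), integrin (0.00775) and VEGF (0.0218) lists up.

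RNA of several other cell types was lower in the Smad4 mutants of the untreated cohort. Of 12 pericyte markers 6 fell (6 adjusted over the list alone), among them Notch3 (-1.07 ± 0.21) and Rgs5 (-1.04 ± 0.27), with a list median of -0.81 and an adjusted p of 0.00358, or adjusted p = 0.555 with an estimated correlation. Smooth muscle markers fell in 5 of 7 cases, neuron markers in 9 of 13 (11 adjusted over the list alone). Oligodendrocyte markers fell in 4 of 9 (8 adjusted over the list alone) and astrocyte markers in 3 of 10 (5 adjusted over the list alone). The medians of these 4 lists were -1.06, -1.54, -1.47 and -1.24. Erythroid markers fell in 4 of 5 cases, with Hbb-bt at -1.61 ± 0.12. Microglia markers, with a median of -0.45 (adjusted p = 0.282), and neutrophil, platelet and lymphocyte markers were not called by camera. With the library code as a term camera did call the microglia list down (adjusted p = 0.0479), and fry called the lymphocyte list down (adjusted p = 0.0175). The dissociation and immediate early list was called down, with 4 of 17 genes lower and a median of -0.42 (adjusted p = 0.0112, or adjusted p = 0.564 with an estimated correlation, 0.19 with the marker level in the fit and 0.138 by fry). Adjusted p was 0.00971 for smooth muscle, 0.00501 for neurons, 0.00568 for oligodendrocytes, 0.0158 for astrocytes and 0.000703 for erythroid cells, and with an estimated correlation it was 0.544, 0.544, 0.544, 0.564 and 0.271. With the glial and neuronal marker level in the fit, the calls of the pericyte (0.236) and smooth muscle (0.362) lists and of Notch3 (adjusted p = 0.0741) and Rgs5 (adjusted p = 0.255) were lost. In all, 19 of the 33 lists were called in this cohort, 0 by camera with an estimated correlation, where 5 had an unadjusted p under 0.05.

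After loss of Alk1, hypoxia, cell cycle and sprouting genes rose and arterial and capillary genes fell. Egln3, an oxygen-sensing hydroxylase (3.93 ± 0.18, adjusted p = 1.06e-07), Slc16a3, a lactate exporter (3.63 ± 0.17, adjusted p = 1.06e-07), and Kcne3, a potassium channel subunit (4.14 ± 0.18, adjusted p = 8.12e-08), were among the 6 largest rises. The transcription factor gene Zbtb16 rose most, at 5.78 ± 1.07 (adjusted p = 0.0015), with values of 39, 4594, 5907, 2563 and 1530 in the mutants and 16 to 33 in the wild types. Without Alk1 mutant 1 the log2 fold change was 7.04 for Zbtb16 and 4.64 for the kinase gene Map3k6. The calls of Zbtb16 and of Map3k6 (3.81 ± 0.72, adjusted p = 0.00175) were lost among the 6 libraries without a code (adjusted p = 0.0642 and 0.0566). The largest falls included the arterial gene Gkn3 (-3.12 ± 0.26, adjusted p = 3.68e-06), the vitamin transporter gene Slc5a6 (-2.51 ± 0.23, adjusted p = 8.18e-06) and Ndnf, which encodes a secreted growth factor (-2.48 ± 0.19, adjusted p = 2.3e-06). Of 13655 genes 4541 were called, 2392 higher and 2149 lower, with 812 changed at least 2-fold (531 higher and 281 lower), and 24.5% did not overlap, against 0.794% by chance. The share of calls that were higher, 52.7%, became 41.1% when each library was divided by its total. In the 3 mutants and 3 wild types without a code 2009 genes were called.

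All 37 cell cycle genes rose in the Alk1 mutants (37 adjusted over the list alone), Ccnb1 by 1.42 ± 0.08, with a median of 1.07 (adjusted p = 2.86e-27, or adjusted p = 0.201 with an estimated correlation). Of 27 hypoxia and glycolysis genes 24 rose (25 adjusted over the list alone), including Ldha and Pgk1 (median 1.03, adjusted p = 2.28e-17, or adjusted p = 0.201 with an estimated correlation). Of 22 tip cell genes 19 rose and 2 fell (19 and 2 adjusted over the list alone), with Pgf at 3.41 ± 0.15 and Trp53i11 at 1.83 ± 0.10 (adjusted p = 4.78e-11, or adjusted p = 0.201 with an estimated correlation). Leukocyte adhesion and chemokine genes rose in 10 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone), with Sele and Cxcl2 up and Vcam1 down (adjusted p = 0.000409, or adjusted p = 0.216 with an estimated correlation). Arterial genes fell in 13 of 18 cases and rose in 2 (14 and 2 adjusted over the list alone), with Sema3g and Vegfc lower (adjusted p = 1.47e-05, or adjusted p = 0.201 with an estimated correlation). Capillary genes fell in 10 of 13 cases and rose in 2, with Spock2 and Cxcl12 lower, and Wnt pathway genes such as Notum and Nkd1 fell in 13 of 21 cases and rose in 1. Both lists had an adjusted p of 1.47e-05, or adjusted p = 0.201 with an estimated correlation. The BMP9-ALK1 response list fell in 10 of 18 cases and rose in 2 (10 and 3 adjusted over the list alone), led by Id1, Id3 and Gja5 (adjusted p = 0.00421, or adjusted p = 0.201 with an estimated correlation).

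Neither pericyte nor interferon response genes were called as lists in the Alk1 cohort. Pericyte markers had a median of -0.20 with Vtn lower (-1.38 ± 0.17), and the 21 interferon genes a median of -0.11. Smooth muscle markers fell in 5 of 7 cases, with Myh11 at -1.03 ± 0.13 (adjusted p = 0.00257, or adjusted p = 0.21 with an estimated correlation). Erythroid markers fell in 4 of 5 cases (adjusted p = 0.00337, or adjusted p = 0.21 with an estimated correlation). The 4 neutrophil markers measured rose, S100a8 and S100a9 most (adjusted p = 0.0158, or adjusted p = 0.228 with an estimated correlation), from low wild-type means of 4 and 13. Genes of dissociation and immediate early responses were called up with 4 of 17 higher, among them Socs3 and Ier3 (adjusted p = 0.00795, or adjusted p = 0.658 with an estimated correlation, and 0.139 by fry). Of the 33 lists 15 were called, 0 by camera with an estimated correlation, where 8 had an unadjusted p under 0.05.

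Loss of Eng gave smaller changes, in fold and in number. The 6 largest rises were in Eda2r (4.89 ± 0.18, adjusted p = 9.64e-09), Phlda3 (3.35 ± 0.07, adjusted p = 4.36e-11), the zinc finger gene Zfp365 (3.07 ± 0.10, adjusted p = 1.89e-09), Dcxr, Ephx1 and Gtse1. Dcxr and Ephx1 encode detoxifying enzymes and Gtse1 a cell cycle protein. Below Eng itself, the largest falls included Efcc1 (-1.15 ± 0.13, adjusted p = 9.61e-05), the monooxygenase gene Fmo1 (-1.15 ± 0.09, adjusted p = 7.97e-06) and the selenium carrier gene Selenop (-1.12 ± 0.08, adjusted p = 2.37e-06). The falls of Slc6a17 and Lrrn3 (-1.41 ± 0.12 and -1.35 ± 0.10) lost their calls in a joint fit of the 30 untreated libraries (adjusted p = 0.0875 and 0.2). Of 14350 genes 3082 were called, 1779 higher and 1303 lower, with 139 changed at least 2-fold (120 higher and 19 lower), and 16.5% did not overlap, against 0.794% by chance. The joint fit called 1602.

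As after loss of Alk1, all 37 cell cycle genes rose in the Eng mutants (37 adjusted over the list alone), with Ccnd1, Plk1 and Mcm5 among them (median 0.70, adjusted p = 1.53e-31, or adjusted p = 0.298 with an estimated correlation). Interferon response genes rose in 14 of 22 cases (18 adjusted over the list alone), among them Bst2 and Rsad2 (median 0.95, adjusted p = 5.12e-08, or adjusted p = 0.469 with an estimated correlation). Their log2 fold changes, Bst2 first, were 1.11 and 2.07 in the 4 mutants and 4 wild types of code L210, against 0.18 and 0.26 in the 1 mutant and 1 wild type of L216. Tip cell genes rose in 13 of 22 cases and fell in 2 (14 and 2 adjusted over the list alone), with Apln at 1.27 ± 0.06 (adjusted p = 1.99e-05, or adjusted p = 0.451 with an estimated correlation). Hypoxia and glycolysis genes such as Gapdh and Ldha rose in 17 of 27 cases, with a median of 0.23 (adjusted p = 1.24e-07, or adjusted p = 0.298 with an estimated correlation). Blood-brain barrier genes fell in 19 of 26 cases (19 adjusted over the list alone) and capillary genes in 11 of 13 (11 adjusted over the list alone), with Slc22a8, Abcb1a, Cxcl12 and Spock2 lower. Both lists had an adjusted p of 1.23e-08, or adjusted p = 0.469 and adjusted p = 0.298 with an estimated correlation. BMP9-ALK1 response genes fell in 6 of 18 cases and rose in 1 (6 and 1 adjusted over the list alone), led by Hey1 and Bambi. The median was -0.17 (adjusted p = 0.0222, or adjusted p = 0.494 with an estimated correlation, and 0.0596 by fry). Pan-endothelial markers fell in 8 of 19 cases and rose in 1 (8 and 1 adjusted over the list alone), with a median of -0.13. That list was called by camera (adjusted p = 0.00246, or adjusted p = 0.571 with an estimated correlation) and by fry (adjusted p = 0.0317). Pericyte (median 0.03), astrocyte (-0.34), neuron (-0.40) and microglia (-0.27) marker lists were not called, and 3 of 6 erythroid markers were lower. Of the 33 lists 13 were called, 0 by camera with an estimated correlation, where 3 had an unadjusted p under 0.05.

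**Figure D2:**
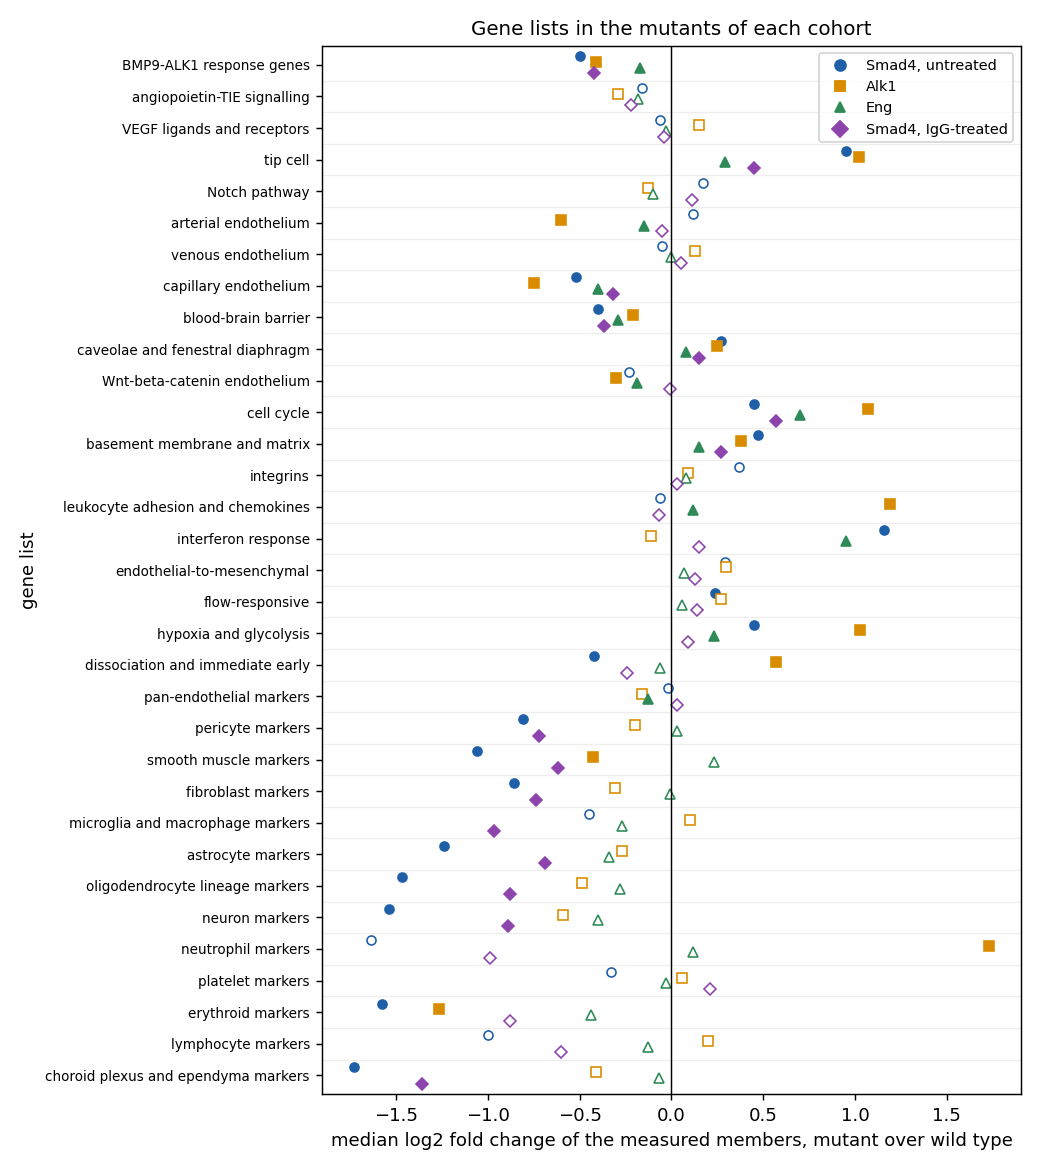
Median log2 fold change (mutant over wild type) of the measured members of each of 33 gene lists, with a circle for the untreated Smad4, a square for the Alk1, a triangle for the Eng and a diamond for the IgG-treated Smad4 comparison, filled where camera's adjusted p was under 0.05. The cell cycle list was called up in all 4 comparisons and the capillary list down in all 4, and none of the filled points held with an estimated correlation.

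A shared response was sought in the genes called in all 3 untreated cohorts. Of 13500 genes tested in all, 1069 were called in the same direction in each, 650 higher and 419 lower, where independent lists would share 85.6, and 71 were called in all with mixed directions. The shared count was 463 at an adjusted p under 0.01, 564 with only the Smad4 and Alk1 libraries without a code, and 699 with the glial and neuronal marker level in the fit. The 10 with the largest smallest change all rose, namely Eda2r, Lif, Tnfrsf9, Ppef1, Phlda3, Esr1, Cdkn1a, Zfp365, Cxcl10 and Gtse1. Eda2r rose by 5.16 ± 0.24, 2.96 ± 0.29 and 4.89 ± 0.18 and Cdkn1a by 1.86 ± 0.14, 1.86 ± 0.28 and 1.53 ± 0.12 after loss of Smad4, Alk1 and Eng. Lif, a cytokine gene, rose by 2.85 ± 0.35, 4.00 ± 0.38 and 2.65 ± 0.30 from wild-type means of only 6, 3 and 4. Among the shared genes were 30 of 37 cell cycle genes against 2.93 expected (one-sided Fisher's exact test over genes, which are not independent replicates, adjusted p = 1.23e-25). They also held 15 of 27 hypoxia and glycolysis genes (adjusted p = 3.18e-09), 13 of 22 tip cell genes (adjusted p = 1.25e-08) and 8 of 28 basement membrane and matrix genes (adjusted p = 0.00526), all higher. The shared falls held 9 of 13 capillary genes (adjusted p = 5.22e-07) and 12 of 25 blood-brain barrier genes (adjusted p = 7.44e-07). They also held 7 of 21 Wnt-beta-catenin genes (adjusted p = 0.00455) and 3 of 5 erythroid markers (adjusted p = 0.0181), the latter from another cell type.

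Pairs of cohorts shared 2187 calls of the same direction for Smad4 and Alk1 (747.5 expected of independent lists, 148 opposite), 1713 for Smad4 and Eng (508.6 expected, 80 opposite) and 1566 for Alk1 and Eng (510.2 expected, 111 opposite). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.527, 0.55 and 0.432 and a Spearman rho of 0.566, 0.567 and 0.454. With the marker level in the fit the Smad4 cohort shared 1077 calls with the Alk1 and 1113 with the Eng cohort. The mutants of all 3 cohorts carried Cre and the wild types did not, so the shared part includes any effect of Cre.

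Genotype effects were then tested against each other in 1 fit of the 30 untreated libraries. Between Smad4 and Alk1, 2340 of 14701 genes differed, with the effect in Smad4 the higher for 1142. The largest positive differences were in Lypd1, a receptor modulator gene (4.48 ± 0.28, adjusted p = 4.03e-12), and in the kinase gene Pak6 (3.10 ± 0.20, adjusted p = 8.05e-12). Both genes rose after loss of Smad4 and fell after loss of Alk1. The largest negative difference was that of Zbtb16, at -5.03 ± 1.16 (adjusted p = 0.00285, and -6.29 without Alk1 mutant 1) and the difference for Angpt2 did not pass (-0.42 ± 0.38, adjusted p = 0.504). By list, 14 of 22 interferon genes and 11 of 18 arterial genes had the higher effect after loss of Smad4, and 27 of 37 cell cycle and 16 of 27 hypoxia and glycolysis genes the lower effect. The Alk1 pups also differed in age, in tamoxifen dose and in the days of induction, which cannot be told apart from the gene here.

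Between Smad4 and Eng, 1182 genes differed, or 1816 without Smad4 mutant 3 and 2065 with the library code as a term. Pgf (3.86 ± 0.30, adjusted p = 4.34e-10) had the higher effect after loss of Smad4, and Id1 (-2.23 ± 0.17, adjusted p = 2.48e-10) and Best1 (-2.11 ± 0.24, adjusted p = 7.33e-07) the lower. After loss of Eng, Pgf (0.31, adjusted p = 0.287) and Id1 (-0.28, adjusted p = 0.13) were not called. Fgfbp1, a growth factor carrier gene, fell after loss of Smad4 and rose after loss of Eng (-2.79 ± 0.32, adjusted p = 9.66e-07). Of 22 tip cell genes 13 had the higher effect after loss of Smad4. Angpt2 did so as well (1.25 ± 0.38, adjusted p = 0.0419), but the call was lost without Smad4 mutant 4 or 5, when the difference was 0.998 or 0.977 (adjusted p = 0.0949 and 0.094). It was also lost without Smad4 wild type 1, 2 or 5 (adjusted p = 0.0857, 0.0638 and 0.0567) and Eng mutant 1, 2, 4 or 5 (adjusted p = 0.0643, 0.0738, 0.0668 and 0.0585). The same held for Eng wild type 1, 2, 3 or 5 (adjusted p = 0.0572, 0.0625, 0.0647 and 0.0696) and for a fit without the filter on low values (adjusted p = 0.0559). Between Alk1 and Eng, 2135 genes differed. Angpt2 rose more (1.67 ± 0.38, adjusted p = 0.00358) and Tek fell more (-0.33 ± 0.08, adjusted p = 0.00346) after loss of Alk1. Hif3a, a hypoxia-inducible factor gene, had the higher effect after loss of Alk1 as well (4.07 ± 0.71, adjusted p = 0.000248, and 4.67 without Alk1 mutant 1). Of the lists, 21 of 27 hypoxia and glycolysis, 14 of 37 cell cycle and 13 of 22 tip cell genes had the higher effect after loss of Alk1, and 10 of 18 arterial genes the lower.

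IgG-treated Smad4 mutants, set against IgG-treated wild types, gave a second view of Smad4 loss in independent libraries. All 3 IgG mutants were high in Xist, against 2 of 3 IgG wild types and 2 of 3 LC10 mutants, so sex was not balanced. Pgf rose by 2.94 ± 0.19 (adjusted p = 9.04e-05), Eda2r by 4.55 ± 0.24 (adjusted p = 2.61e-05), and Gdf15, a stress cytokine gene, by 2.89 ± 0.44 (adjusted p = 0.00266, and 2.28 without IgG mutant 3). Id1 (-1.81 ± 0.24, adjusted p = 0.00149), Ddc (-2.26 ± 0.33, adjusted p = 0.00228) and the matrix gene Tnc (-1.71 ± 0.18, adjusted p = 0.000459) fell. Angpt2 rose from 1720 ± 93.9 to 3280 ± 1150 (0.88 ± 0.24, adjusted p = 0.0282). The call was lost without IgG mutant 3 (0.611, adjusted p = 0.0698), without any 1 of the 3 wild types (adjusted p = 0.0722, 0.0711 and 0.054). It was likewise lost with Xist (adjusted p = 0.0631) or the glial and neuronal marker level (adjusted p = 0.09) in the fit. Tek fell by 0.34 ± 0.07 (adjusted p = 0.0108). Of 14052 genes 3371 were called, 1849 higher and 1522 lower, with 528 changed at least 2-fold (130 higher and 398 lower). The share that was higher, 54.9%, became 45.5% when each library was divided by its total. Without IgG mutant 2, mutant 3 or wild type 2 the count was 1758, 2166 or 2152. It was 5727 with array weights, 2260 with Xist in the fit and 1900 with the marker level in the fit. A fit of the 2 IgG groups alone, without the LC10 libraries, called 2480. The groups did not overlap for 40.9% of genes, against 10% by chance. Of the 4581 genes called in the untreated Smad4 cohort and tested here, 95.9% had the same direction, and 2263 were called in both with the same direction, against 557.5 expected and 1 opposite. Across all genes tested in both, which are not independent replicates, the fold changes had a Pearson r of 0.797. With the marker level in the fit 813 calls were shared.

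By list, cell cycle genes rose in 35 of 37 cases (37 adjusted over the list alone; adjusted p = 3.54e-16, or adjusted p = 0.615 with an estimated correlation), Plk1 and Tyms among them. Tip cell genes rose in 12 of 22 cases (13 adjusted over the list alone), with Apln at 1.12 ± 0.08 (adjusted p = 1.01e-06, or adjusted p = 0.597 with an estimated correlation). Matrix genes rose in 14 of 28 cases and fell in 2 (16 and 2 adjusted over the list alone), Col18a1 by 1.92 ± 0.13 (adjusted p = 0.00121, or adjusted p = 0.615 with an estimated correlation). Blood-brain barrier genes such as Abcb1a and Slc19a3 fell in 14 of 26 cases and rose in 2 (16 and 3 adjusted over the list alone; adjusted p = 0.000557, or adjusted p = 0.615 with an estimated correlation). The BMP9-ALK1 response list was called down (adjusted p = 0.0277, or adjusted p = 0.597 with an estimated correlation). Its call was lost when each library was divided by its total (adjusted p = 0.0535) and with the marker level in the fit (adjusted p = 0.0808). Interferon genes had a median of 0.15 with 0 of 22 called by limma and 1 at an unadjusted p under 0.05, and hypoxia genes a median of 0.09 with a mean of -0.06. Pericyte markers fell in 7 of 12 cases (10 adjusted over the list alone), with a median of -0.72 (adjusted p = 0.000255, or adjusted p = 0.615 with an estimated correlation, and 0.0978 by fry). Microglia markers fell in 12 of 15 cases (15 adjusted over the list alone), with Cx3cr1 at -1.19 ± 0.23 (adjusted p = 1.05e-06, or adjusted p = 0.615 with an estimated correlation). Fibroblast, astrocyte, oligodendrocyte and neuron lists had medians of -0.74, -0.69, -0.88 and -0.89.

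The last question was whether inhibition of angiopoietin-2 by LC10 moved the mutants back towards the wild type. The LC10 libraries were normalized in a table of their own, with no wild type among the samples described, so values were brought to a common scale and no test was made. On that scale Angpt2 stood at 6190 ± 2060 in the LC10 mutants, 3002 ± 1050 in the IgG mutants and 1572 ± 80.3 in the IgG wild types (n = 3 each). Apln stood at 41159 ± 2420, 27528 ± 1740 and 12736 ± 1150, and Pgf at 598 ± 39.5, 629 ± 193 and 78 ± 6.5. Id1 stood at 1150 ± 101, 1835 ± 835 and 6095 ± 835, and Tek at 20439 ± 441, 22782 ± 2590 and 28792 ± 306. Genes higher in the untreated Smad4 mutants had a median difference of -0.01 between LC10 and IgG mutants, and genes lower there of 0. A score of these genes, the mean log2 value of those higher minus that of those lower, was 1.37 ± 0.02 in IgG wild types, 2.27 ± 0.29 in IgG mutants and 2.22 ± 0.15 in LC10 mutants. The difference of -0.05 between treatments was well under the range of 0.4 among the wild-type means of the 4 cohorts. Of 3368 genes called between IgG mutants and wild types, 61% moved back under LC10, and 60.4% (58.4 to 62.4 in 100 simulations) did so in simulated data with no effect of LC10, since both contrasts share the IgG mutants.

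**Figure D3:**
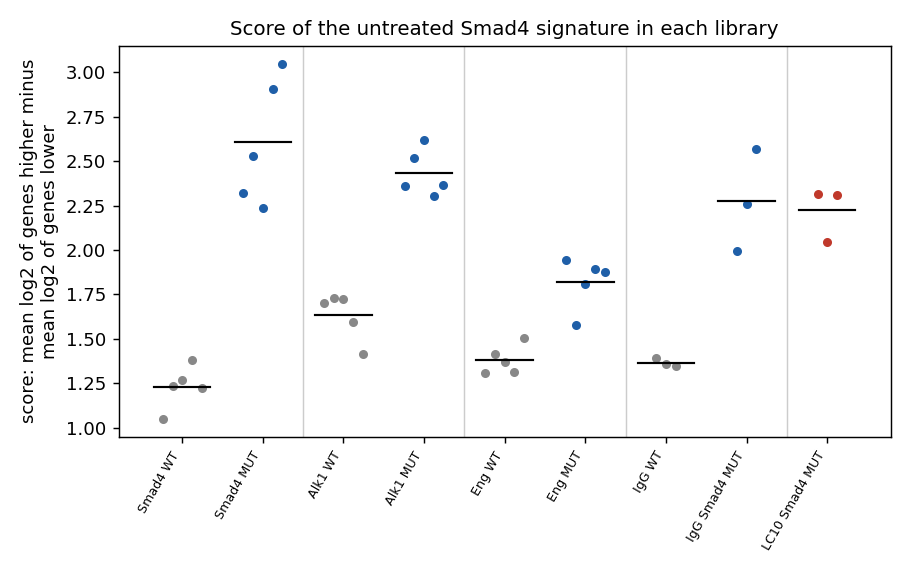
Score of the untreated Smad4 signature in each library, defined as the mean log2 value of the genes higher in mutants minus that of the genes lower, with wild types in grey, mutants in blue, LC10-treated mutants in red and group means as black lines. LC10 mutants averaged 2.22 and IgG mutants 2.27, both above the IgG wild types at 1.37.

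Single gene groups did differ between LC10 and IgG mutants in level. Pericyte markers had a median difference of -0.91, all 12 lower and 7 without overlap. BMP9-ALK1 response genes (median -0.33) and arterial genes (median -0.22) were each lower without overlap in 7 of 18 cases and higher in 1. Venous genes (median -0.23) were lower without overlap in 7 of 17 cases, and VEGF ligands and receptors in 4 of 11, with 1 higher. Flow-responsive genes were higher without overlap in 6 of 14 cases and lower in 1. Of 37 cell cycle genes 36 were lower (median -0.17), but only 21.6% stood without overlap. All 17 dissociation and immediate early genes were higher (median 0.40), with 23.5% without overlap. Astrocyte, oligodendrocyte and neuron markers had medians of 0.64, 0.76 and 0.76. The largest differences without overlap were higher levels of Slc6a17 (2.46), Gdf15 (1.59), the axonal adhesion gene Cntn2 (1.42) and the myelin gene Mbp (1.31), and lower levels of Fam174b (-2.16), Tll1 (-1.53), Moxd1 (-1.35) and Cbln2 (-1.33), besides Xist, which follows the sex of the pups. Groups did not overlap for 18.4% of 14049 genes, against 10% by chance.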

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

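The tests in this part were chosen after the results were seen, except for the counts over other splits of the samples, which were planned. Single libraries stood apart in 12 of 190 groups of 5 values examined, where the gap to the nearest other library was over 0.71 of the range, and chance gives about 1 in 20. In Alk1 mutant 1, Cbln2 was 415 (76.8 to 105 in the others, ratio 0.915), Sgpp2 299 (137 to 168, 0.805) and Dkk2 604 (181 to 293, 0.735), so this library had the smallest fall in these 3 genes. Eng was 47000 in Alk1 mutant 2 (35000 to 38300, 0.728). In Eng mutant 3, Angpt2 was 6550 (4250 to 4650, 0.828) and Gtse1 1890 (1650 to 1710, 0.749). Smad4 was 6870 in Eng wild type 1 (7440 to 7630, 0.755) and 7310 in Eng mutant 5 (6630 to 6810, 0.74), and Fmo1 was 2060 in Smad4 wild type 1 (968 to 1250, 0.746). Choroid plexus markers were 4660 ppm of the summed values in Smad4 wild type 1 (918 to 1670, 0.798) and 170 in Alk1 mutant 3 (645 to 778, 0.781), and smooth muscle markers 297 ppm in Alk1 wild type 2 (253 to 262, 0.792).

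Genotype effects on named genes differed between cohorts, by the test of the difference, in the 27 cases given here. For Smad4 minus Alk1 the differences in log2 fold change were 4.48 for Lypd1, 3.1 for Pak6, 3.07 for Rec8, -2.72 for Spp1, -2.74 for Rab15, -5.03 for Zbtb16, -1.79 for Smad4, 0.27 for Acvrl1, 0.82 for Eng and 0.28 for Tek. For Acvrl1 the call was lost without Alk1 mutant 1, 4 or 5, Alk1 wild type 2, 3 or 4, Smad4 mutant 2 or 5 or Smad4 wild type 1, 2 or 5, with differences of 0.249, 0.26, 0.226, 0.238, 0.258, 0.273, 0.254, 0.249, 0.25, 0.253 and 0.273. For Smad4 minus Eng they were 3.86 for Pgf, 3.61 for Lypd1, -2.11 for Best1, -2.23 for Id1, -2.79 for Fgfbp1, -1.53 for Smad4, 3.1 for Eng and 1.25 for Angpt2, and for Alk1 minus Eng 6.75 for Zbtb16, 4.07 for Hif3a, 3.62 for Map3k6, -2.4 for Fgfr4, -2.62 for Gkn3, -3.48 for Rec8, 2.29 for Eng, 1.67 for Angpt2 and -0.33 for Tek. Smad4 and Eng are the deleted genes of their cohorts. Age and tamoxifen also differ for Alk1.

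Other splits of the libraries show how often a count of genes as high arises by chance. For the untreated cohorts 1 of 100 splits, the real one, gave as many genes. The highest other split called 2 against 4620 in the Smad4, 7 against 4541 in the Alk1 and 14 against 3082 in the Eng cohort. With 100 splits 1 of 100 is the lowest share that can be found, so chance is unlikely but not excluded. Splits that mix genotypes also put the genotype effect into the spread, which lowers their counts. They do not tell loss of the gene from another difference between the groups, such as Cre. For IgG the 10 splits are too few for a share under 0.05, with 3371 genes in the real split and 5 in the highest other. For the differences between cohorts, genotype labels were permuted within cohorts. Between Smad4 and Eng 1 of 100 gave as many as the real 1182, with 61 in the highest other. Between Smad4 and Alk1 2 of 100 did, with 4004 against the real 2340, and between Alk1 and Eng 3 of 100, with 4534 against 2135. These high ones swapped 4 or all 5 mutants of 1 cohort and few of the other, which turns the difference of effects into their sum, so they point to the structure that the shared genotype effect gives the samples.

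The first pattern weighed is the rise of p53 target genes in the mutants of all 3 untreated cohorts, with mean log2 fold changes of 1.09, 0.57 and 1.05 after loss of Smad4, Alk1 and Eng. The errors in this paragraph are taken over the genes of a list, which are not independent replicates. In the Eng cohort p53 targets rose by 1.05 ± 0.17, while immediate early genes moved by -0.06 ± 0.04 with 0 of 17 called. By library, the mean log2 value of 44 p53 targets was 10.51 to 10.64 in Eng mutants and 9.52 to 9.58 in their wild types. Stress of dissociation is thus argued against in that cohort. A larger share of RNA from the same other cell type in every cohort is argued against, since 0 of 12 marker lists of other cell types were higher in all 3. This check cannot see cell types that differ between cohorts, or a rise within other cells, so these stay open. Immediate early genes had a median of -0.42 in the Smad4 cohort, a call lost with an estimated correlation (adjusted p = 0.564). In the Alk1 cohort they had a median of 0.57, so dissociation stays open there. Tamoxifen alone is argued against, since mutants and wild types of a cohort received the same dose on the same days. Cre activated by tamoxifen stays open and cannot be told apart from gene loss, since every mutant and no wild type carried Cre. The rise was larger by 0.50 ± 0.12 in the Smad4 than in the Alk1 cohort, which received less tamoxifen. The Alk1 pups were also induced later and collected younger, so that gap does not single out the dose.

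The second is the lower pericyte marker RNA in Smad4 mutants. In the untreated cohort a mean of -0.75 ± 0.30 became -0.26 ± 0.36 with the glial and neuronal marker level in the fit, so the call ended through a smaller change with a larger error, and a lower share of all other cells after capture cannot be told apart from fewer pericytes. In the IgG cohort the mean went from -0.71 ± 0.28 to -1.07 ± 0.39, but that fit held only 6 libraries, too few to decide. Microglia (mean -0.99) and fibroblast (-0.68) markers, which are not in the covariate, fell there as well, while platelet markers did not (0.04). A lower share of other cells thus stays open in the IgG cohort too. A shift common to all libraries of a code could not produce the fall in the untreated cohort, since each code held as many mutants as wild types. Within both sets the mutants were lower, with -0.47 ± 0.16 in libraries without a code and -1.17 ± 0.54 in those of L146. The latter rests on only 2 mutants and 2 wild types. A weaker attachment of pericytes during dissociation was not tested.

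The third is Angpt2 in the Smad4 cohort, at 22452 and 23827 in the 2 mutants of code L146 and 6524 to 7271 in the 3 without, a ratio of means of 3.39. A library batch acting on all samples is argued against by the wild types, whose ratio was 1.09. Less complete deletion in the mutants without a code is argued against by Smad4 itself, with a ratio of 1.07, and dilution by RNA of other cells by pan-endothelial markers, with a ratio of 1.13. The difference was not limited to Angpt2. The signature score was 2.909 and 3.049 in the same 2 mutants and 2.239 to 2.532 in the 3 without, though that score includes markers of other cells. A stronger response of the mutants with that code, whose meaning the labels do not give, is left as a hypothesis and was not tested.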

How the results depend on the processing

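Total and quantile scaling, pseudocounts, array weights, library codes and the brain-cell marker covariate were alternatives chosen after the data had been seen, and the others were planned. With the covariate, the mean of astrocyte, oligodendrocyte and neuron markers, the count of called genes fell to 2098 for Smad4 and 1900 for IgG, the shared count of all 3 cohorts to 699, and the overlaps to 1077 (Smad4 and Alk1), 1113 (Smad4 and Eng) and 813 (untreated and IgG Smad4). Of the 4620 genes called in the Smad4 cohort 1788 were still called with it. It reversed the direction of the astrocyte (adjusted p = 0.0748), microglia (0.00973) and oligodendrocyte (0.514) lists in the Smad4 and of the neuron and oligodendrocyte lists (0.831 for both) in the IgG comparison, and of Aldh1l1 in the Smad4 cohort (log2 fold change 0.03), which for markers that make up the covariate follows from its construction. Libraries without a code alone gave 2461 genes for Smad4, 2009 for Alk1 and 564 shared by all 3, and those of code L146 alone reversed Ltf (log2 fold change -1.087) in the Smad4 cohort. The code as a term gave 2065 for Smad4 against Eng. The joint fit gave 1602 for Eng, array weights 5727 for IgG, and a threshold of 0.01 left 463 shared genes. For these the cause was not tested.

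Leaving out 1 library at a time gave 3363 to 5622 genes for Smad4, 3862 to 4885 for Alk1, 2420 to 3152 for Eng, 1758 to 3798 for IgG, 927 to 1094 for all 3, 2037 to 2791 for Smad4 against Alk1, 802 to 1816 for Smad4 against Eng, 1652 to 2768 for Alk1 against Eng, and -0.191 to 0.097 for the difference in signature score between LC10 and IgG mutants. The lowest for IgG was without IgG mutant 2 (1758), with 2166 without mutant 3 and 2152 without wild type 2, and the highest for Smad4 against Eng was without Smad4 mutant 3. Of 11433 values of 539 results for named genes 10768 kept their call and direction, 501 lost the call, 162 gained one and 2 were reversed. Of 891 values for differences between cohorts 860 kept it, 26 lost it and 5 gained one, and of 792 values for lists 668 kept it, 90 lost it, 29 gained one and 5 were reversed.

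A block for the replicate number moved the IgG count from 3371 to 3862. Same-numbered IgG wild types and mutants correlated at 0.043, 0.025 and -0.069 and IgG and LC10 mutants at -0.016, 0.064 and 0.133, and not every sample correlated best with its own number, so the samples share only a number. No pairing by number was possible for the 3 untreated cohorts because their columns carry no numbers that map to samples. Library codes did mark blocks there, each with as many mutants as wild types. With the code as a term 6428, 5147 and 3520 genes were called for Smad4, Alk1 and Eng, against 4620, 4541 and 3082 without it. In the Smad4 and Alk1 cohorts libraries without a code held 11.11M to 16.05M fragments and those with one 19.57M to 30.17M. The planned tests for counts and tests of LC10 were not run, since the values are not counts and LC10 lies in a table of its own.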

Other observations

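The tests in this part were all chosen after the values had been seen. Eda2r and Phlda3, known targets of p53, were among the 6 largest rises in both the Smad4 and the Eng cohort. For this reason 45 p53 target genes were examined as a group. After loss of Smad4 34 rose and 4 fell, with a mean log2 fold change of 1.09. After loss of Eng 31 rose and 2 fell, with a mean of 1.05, and after loss of Alk1 23 of 44 rose and 3 fell, with a mean of 0.57. With an estimated correlation in camera the adjusted p was 0.000176, 0.000176 and 0.0019, and in the IgG cohort, where 28 rose and 3 fell, 0.133. Without the 5 leading genes Eda2r, Phlda3, Zfp365, Pvt1 and Gtse1 the means were 0.82, 0.78 and 0.42 in the Smad4, Eng and Alk1 cohorts and 0.62 in the IgG cohort. The shorter list first run gave adjusted p of 0.000354, 0.000354, 0.0297 and 0.212 for Smad4, Eng, Alk1 and IgG with an estimated correlation. Of the 10 genes of largest shared change 5 are in this list, which was drawn up after they had been seen. As a hypothesis, the shared rise may in part reflect DNA damage from Cre recombinase. The rise was larger by 0.50 in the Smad4 than in the Alk1 cohort, which received less tamoxifen. The Alk1 pups were also induced later and collected younger, so that gap does not single out the dose. No wild type carried Cre, and the hypothesis was not tested.

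Glucocorticoid-responsive genes rose in the Alk1 mutants, where 15 of 24 were higher, with a mean log2 fold change of 1.68 (adjusted p = 4.96e-07 by camera and 0.35 with an estimated correlation). Against the Eng cohort 17 of 24 had the higher effect (0.0964 with an estimated correlation). In the Alk1 mutants Zbtb16 was 39, 4594, 5907, 2563 and 1530, against 16 to 33 in the wild types, Fkbp5 1424 to 3845 against 710 to 797, Per1 2142 to 16680 against 1264 to 1642 and Hif3a 391 to 7202 against 64 to 207, and Alk1 mutant 1 was the lowest mutant in all 4. In the Smad4 cohort 11 rose and 5 fell, in the Eng cohort 3 rose and 6 fell, and in the IgG cohort 2 rose and 4 fell. Illness of the pups on the day of collection is a hypothesis that the labels give no means to test.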
